A study of Gallus gallus with 4 samples.

How the data were processed

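The data are 4 Affymetrix chicken genome arrays, 2 of PR9692 cells with a control shRNA and 2 with an anti-HOPX shRNA, grouped by the sample titles. Per the labels' protocols, total RNA from cultured cells was converted to biotin-labelled cRNA by the standard Affymetrix procedure. The deposited values are on the log2 scale, 1 per probe set and array. GCRMA and Partek 6.4 are named in the submitters' processing notes without their roles. GCRMA corrects the background with a model of probe sequence, normalises the arrays to each other and summarises the probes of a probe set. This pulls probe sets with little signal towards a narrow floor, which makes the fold change of a gene that is silent in either form depend on the background model, and it removes any overall difference in RNA amount between arrays. The version of GCRMA, further filtering and the scanner settings are not given in the sources used here. No detection calls were used, and the scale was read from the values, which run from 0.75 to 15.97.

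The table holds 38535 probe sets. The 96 Affymetrix control probe sets were left out of the tests and used for checks of the arrays. Probe sets were kept where the mean over the 4 arrays was at least 4, which left 14851. HOPX was tested whatever its level. Genes were named from the platform's annotation, in which 27168 probe sets have 1 gene, 177 have several and 11094 have none. Symbols were updated through the gene identifiers of a RefSeq gene table for the assembly GRCg7b, which held 98.8% of the identifiers of the probe sets with 1 gene, and the platform's symbol was kept otherwise. Probe sets with several genes or none were tested but not named. A gene was represented by its probe set with the highest mean, which gave 7702 genes. The kept probe sets of a named gene did not disagree in sign past the threshold.

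The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), without a replicate block, and p-values were adjusted by the Benjamini-Hochberg method over the kept probe sets. Counts of changed probe sets require an adjusted p under 0.05 and at least a 2-fold change, and a gene of a list rose or fell where its adjusted p was under 0.05. Tests of genes, lists and chromosome medians are two-sided, and those of neighbouring genes ask only for more adjacent genes than random orders give. With 2 arrays against 2, an exact permutation test cannot go below p = 0.33, so the calls rest on limma's spread, which is shared across probe sets (2 residual degrees of freedom, prior of 3.54). A gene with an array value under 4 has its fold given as a lower bound, with single array values under 4 raised to 4. Errors of group means are SDs over 2 arrays.

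The 31 gene lists hold 1268 symbols, of which 1189 were matched to a gene, and cover matrix, adhesion, signalling, proliferation, stress, immune and cell type genes. They were compared with all other genes by limma's camera test, on lists with 5 or more measured members, adjusted over the lists. The result of 1 list, and 1 gene that the rule below names in another, are not reported here. The lists, the groups, the tests, the alternatives and the rule for naming genes were set before the data were examined. By that rule HOPX, EGR1, SRC, GAPDH and ACTB are always named, then the 12 genes with the largest change each way among those past the threshold whose arrays do not overlap between forms, and from each list up to 4 members that passed and up to 2 that did not, by size of change. Alternatives were other filters on low values, variance models and normalisations, stricter thresholds, genes in place of probe sets, an estimated correlation or limma's fry, which tests a list against no change, for the lists, the replicate number as a block, and leaving out each array in turn.

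The procedure was tested on simulated data with the spread of these arrays, 14851 probe sets and 200 changed ones in each of 10 runs. Calls there needed only an adjusted p under 0.05, without the 2-fold minimum used for the counts. The procedure recovered 18.0% of changes of 1 on the log2 scale, 84.0% of changes of 2, 95.6% of changes of 3 and 99.4% of changes of 5. Of the calls 5.65% were false. The simulated spread was the same in both forms, whereas the real anti-HOPX arrays lay farther apart than the control arrays. A simulated shift of 0.7 of the interferon list, on 7702 genes, was called in 20 of 20 runs by camera with the preset correlation, in 0 with an estimated correlation and in 5 by fry. The simulated genes varied independently, so the preset correlation was close to true by construction. In the data the estimated correlation of this list was 0.30, so these runs do not show which correlation to use. The design gives no batch. Positions in GRCg7b were used only to find which genes neighbour each other or share a chromosome and to take gene lengths.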

Results

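Gene expression was measured in PR9692, a cell line derived from a chicken sarcoma, in 2 stably transfected forms. One form carried a control short hairpin RNA (shRNA) and the other an shRNA against HOPX, which codes for a small homeodomain protein that lacks DNA binding of its own. The series' design text describes the control form as metastatic and the anti-HOPX form as non-metastatic, so the comparison asks which transcripts differ between a metastatic and a non-metastatic form of the same line. Each form was represented by 2 Affymetrix chicken arrays, 4 arrays in all, hybridised with biotin-labelled cRNA from total RNA. The labels call the arrays of a form biological replicates, but they do not say whether these were separate cultures, or whether each form was a clone or a pool of transfected cells. The p-values below therefore measure the spread between these arrays, and the number of arrays limits the precision.

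All values are GCRMA values on the log2 scale, and differences are anti-HOPX minus control. The 4 arrays had similar distributions, with medians from 3.12 to 3.15 over all probe sets. Over the 14851 probe sets kept for testing, Pearson's r across probe sets was 0.992 between the control arrays and 0.985 between the anti-HOPX arrays, against 0.954 to 0.959 for the 4 pairs of arrays from different forms. Probe sets are not independent replicates, so these correlations only describe the arrays. The anti-HOPX arrays lay farther apart than the control arrays, with a median absolute difference of 0.25 against 0.16 over the kept probe sets. The gap between the 3' and 5' control probe sets of beta-actin, a measure of RNA integrity, averaged 2.84 in control and 2.93 in anti-HOPX arrays. The same gap averaged 0.07 and 0.08 for GAPDH. For EF1A it was 2.03 and 1.99 on the control arrays, but 1.87 and 2.35 on anti-HOPX replicates 1 and 2. The poly-A controls averaged 8.86 in control and 8.62 in anti-HOPX arrays. None of the 96 control probe sets passed the threshold of the comparison with limma, with 1 at an unadjusted p under 0.05.

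The targeted gene, HOPX, was near the background in both forms. Its brighter probe set read 3.23 and 3.72 on the control arrays and 3.21 and 3.54 on the anti-HOPX arrays, a difference of -0.10 (SE 0.25, limma adjusted p = 0.85). Its other probe set read 3.08 and 3.23 on the control arrays against 3.05 and 2.92 on the anti-HOPX arrays, a difference of -0.17 (SE 0.19, limma adjusted p = 0.63). Control probe sets with no chicken target read between 1.86 and 2.89, and both HOPX probe sets lay under the mean of 4 required for testing other probe sets. No fold change is given, because both forms were at the low end of the scale. The sign of the difference of the brighter probe set turned without control replicate 2, at 0.15, and without anti-HOPX replicate 1, at 0.07. The arrays thus neither showed nor excluded a lower HOPX transcript level, and HOPX does not serve here as a check of the labels.

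Many other genes differed. Of the 14851 probe sets tested, 315 were higher and 499 lower in the anti-HOPX cells by at least 2-fold at an adjusted p under 0.05. At each of these 814 both arrays of a form lay beyond both arrays of the other, which this threshold nearly requires with 2 arrays per form. Counted as genes with 1 probe set each, 176 were higher and 293 lower. By 3 or more on the log2 scale, 46 of the called probe sets were higher and 100 lower, or 39 and 62 with array values under 4 raised to 4. Among the genes with the largest rise were TIMP3, a secreted inhibitor of metalloproteinases that binds to the extracellular matrix, which went from 5.07 ± 0.35 (SD, n = 2) to 11.55 ± 0.21, and GEM, a small GTP-binding protein of the RGK family, which went from 5.06 ± 0.06 to 10.87 ± 0.43. These are rises of 89.7-fold and 56.1-fold. AADAC, a microsomal esterase, rose 24.6-fold, though its second tested probe set differed by 0.25 (limma adjusted p = 0.51). For the other 9 of the 12 genes with the largest rise, the control level was under 4, where GCRMA values are dominated by background, so the fold was bounded by raising values under 4 to 4. MALL, a membrane raft protein, rose at least 47.0-fold to 9.56 ± 0.31, NREP, a regulator of neuronal regeneration, at least 40.5-fold, and FAM132A, an adipokine of the C1q and TNF related family, at least 30.4-fold. The same bound was 19.5-fold for the matricellular protein POSTN (periostin), 18.2-fold for the transcription factor KLF15, 14.3-fold and 12.6-fold for the keratins KRT7 and KRT5, 11.2-fold for the complement protease CFI and 9.99-fold for the complement chain C1QB. The second tested probe set of POSTN reached 4.78 and was higher by at least 1.72-fold, which did not pass (limma adjusted p = 0.16). The order of the genes is that of the unbounded differences, and by the bound KRT75, TSHZ3 and OLFM3 would take the places of KRT5, CFI and C1QB among the 12.

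The 12 genes with the largest fall all ended under 4 on the anti-HOPX arrays. MVP, the major protein of vault particles, went from 10.01 ± 0.11 (SD, n = 2) to 1.88 ± 0.26, a fall of at least 64.6-fold, and HTR1D, a serotonin receptor, from 11.30 ± 0.20 to 3.71 ± 0.02, at least 157.2-fold. DHRS7, a short-chain dehydrogenase, fell at least 54.1-fold, the organic cation transporter SLC22A3 at least 46.8-fold, and the membrane protein TMEM26 at least 39.7-fold. NUDT14, a nucleoside diphosphate sugar hydrolase, fell at least 37.0-fold. APBB1IP, a Rap1 effector that promotes integrin activation, fell at least 33.6-fold, glutathione reductase (GSR) at least 31.5-fold, and PDGFRL, a protein related to platelet-derived growth factor receptors, at least 27.9-fold. The bounds for the small GTPase RAB15, for GFPT2, an enzyme that feeds the hexosamine pathway, and for HSBP1L1 were 22.2-fold, 20.4-fold and 16.3-fold, and by the bound PLXNC1, RSPO3 and FBLN1 would take the places of these 3. The limma adjusted p of these 24 genes ranged from 3.6e-04 for MVP to 0.023 for CFI. The counts depended on the control arrays, which lay closest together: without control replicate 1, 39 probe sets were higher and 115 lower, and without control replicate 2, 34 and 108. Of the 24 genes, 21 still passed without control replicate 1 and likewise 21 without control replicate 2, and KLF15, KRT7 and CFI did not in either case.

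**Figure D1:**
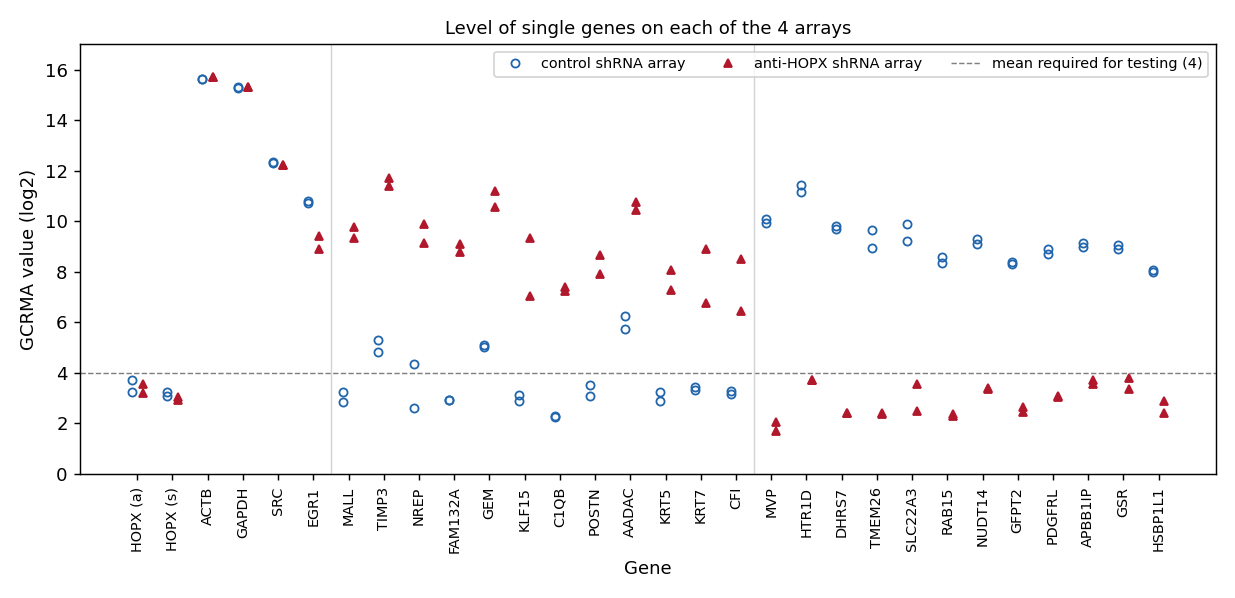
GCRMA values (log2, vertical axis) of single genes on each of the 4 arrays, with open circles for the control shRNA arrays, filled triangles for the anti-HOPX shRNA arrays and a dashed line at 4, the mean required for testing. HOPX is shown for its brighter (a) and its other (s) probe set, followed by ACTB, GAPDH, SRC and EGR1, the 12 genes with the largest rise and the 12 with the largest fall; HOPX lies under the line on all 4 arrays, while MVP goes from 10.01 in control to 1.88.

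EGR1, an immediate early transcription factor induced by growth signals, fell from 10.75 ± 0.06 (SD, n = 2) to 9.16 ± 0.38, a difference of -1.59 (SE 0.21, limma adjusted p = 0.016) and 3.01-fold lower. Its second probe set differed by -1.94 (limma adjusted p = 0.018). The call was lost without control replicate 1 (-1.63, adjusted p = 0.15), without control replicate 2 (-1.54, adjusted p = 0.17) and without the filter on low values (adjusted p = 0.093). The brightest probe set of SRC, the tyrosine kinase whose viral form is the classic sarcoma oncogene, read 12.33 ± 0.05 in control and 12.23 ± 0.02 in anti-HOPX cells (limma adjusted p = 0.59). Its second tested probe set read 4.71 and 4.69 (limma adjusted p = 0.97), and its other probe sets lay under the mean of 4 required for testing. The housekeeping genes ACTB and GAPDH differed by 0.05 (limma adjusted p = 0.70) and 0.03 (limma adjusted p = 0.82), and the sign of GAPDH turned to -0.018 when the arrays were quantile normalised again. Among the 21 measured immediate early genes, EGR1 and the MAP kinase phosphatase DUSP6 (-0.57) fell, KLF2 (1.07) and ETV4 (0.84) rose, and 17 did not pass, MAFF (-1.02) and BTG2 (0.88) among them.

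Of the 31 gene lists fixed in advance, 2 were higher and 1 was lower in the anti-HOPX cells by limma's camera test with its preset correlation of 0.01. The interferon response list shifted most. Of its 29 measured genes 11 rose, 0 fell and 18 did not pass, and 13 rose when adjusted over the list alone. Without the filter on low values, 1 of the 29 rose and 0 fell. The median difference was 0.73, 25 of the 29 members were above 0, and the camera adjusted p was 4.2e-05. This call rests on the preset correlation, since the adjusted p was 0.92 with an estimated correlation between genes. By fry, which tests a list against no change rather than against the other genes, the adjusted p was 0.17 for this list and for the 2 others called by camera. IFI6, an interferon-induced inhibitor of apoptosis, rose by 3.74, from 8.28 ± 0.44 (SD, n = 2) to 12.01 ± 0.84. The antiviral genes OASL and MX1 rose by 2.51 and 2.31, and the nucleotide kinase CMPK2 rose at least 3.43-fold. IFIT5, an RNA-binding antiviral protein, was higher by at least 2.73-fold (limma adjusted p = 0.098) and EPSTI1 by 0.89 (limma adjusted p = 0.35), neither past the threshold. The list of MHC and antigen presentation genes was also higher by the preset correlation (median 0.67, camera adjusted p = 0.018, and adjusted p = 0.92 with an estimated correlation), though 2 of its 10 measured members rose, the class II chaperone CD74 (1.45) and the peptide transporter subunit TAP2 (0.95), and 6 rose when adjusted over the list alone. The peptidase ERAP1 differed by 1.03 and beta-2-microglobulin, B2M, by 0.73, with adjusted p of 0.052 and 0.078. The MHC list was not called by camera without anti-HOPX replicate 1 or with only probe sets of mean 6 or more (adjusted p = 0.055). It was also not called without the probe sets whose names end in _x_at, _s_at or _a_at (adjusted p = 0.50). None of the interferon genes passed singly without control replicate 1 or without control replicate 2, though the list stayed called without each of the 4 arrays in turn.

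The list of cholesterol and lipid synthesis genes was lower (median -0.41, camera adjusted p = 0.017, and adjusted p = 0.92 with an estimated correlation). Of 28 measured members 5 fell, 1 rose and 22 did not pass, and 13 fell and 3 rose when adjusted over the list alone. With no filter on low values, 0 rose and 0 fell. The fatty acid elongase ELOVL6 fell by 1.32, the sterol desaturase SC5D by 1.08 and the cholesterol transfer protein STARD4 by 0.90, while the elongase ELOVL5 rose by 0.78. SCD, the stearoyl-CoA desaturase, and MVK, mevalonate kinase, differed by -1.09 and -0.80 (limma adjusted p of 0.13 and 0.071). The list was not called without control replicate 1 (adjusted p = 0.053) or without anti-HOPX replicate 2 (adjusted p = 0.18).

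Genes of the extracellular matrix and of adhesion moved both ways, and none of their lists shifted as a whole. Among 24 collagens and matrix proteins, 2 rose and 4 fell (camera adjusted p = 0.71). POSTN rose, whereas fibulin-1 (FBLN1) fell at least 22.5-fold, the laminin chain LAMB1 at least 14.3-fold and the collagen COL18A1 3.68-fold, and FBN1 (1.07) and COL5A1 (1.03) did not pass. Among 19 matrix proteases and inhibitors (camera adjusted p = 0.83), TIMP3 rose and the membrane-type metalloproteinase MMP15 fell by 0.88, while SERPINE2 (-1.05) and the gelatinase MMP2 (-0.73) did not pass. Of 16 integrins and integrin-linked genes (camera adjusted p = 0.61), PTK2, the focal adhesion kinase, rose by 1.13 and the integrin chain ITGB5 fell by 1.35, and BCAR1 (-0.74) and ITGA6 (-0.59) did not pass. Of 8 cadherins and neural adhesion molecules (camera adjusted p = 0.36), the protocadherin PCDH1 (2.12) and the tetraspanin CD151 (0.60) rose, and PCDH9 (0.83) did not pass. Adjusted over the list alone, 3 rose and 4 fell among the matrix proteins, 1 and 1 among the proteases and inhibitors, 1 and 3 among the integrins and 3 and 1 among the cadherins.

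Of 20 measured metastasis suppressors, 3 rose, 2 fell and 15 did not pass (camera adjusted p = 0.83; adjusted over the list alone, 4 rose and 2 fell). TIMP3, the kinase MAP2K4 (1.64) and NDRG1 (0.86) rose, and CASP8, named after its value was seen, fell by 0.62. CD44, the hyaluronan receptor, differed by -0.89 and NME3 by 0.64, neither past the threshold. Of 17 mesenchymal genes and regulators of the epithelial to mesenchymal transition, MSX2 (1.06) and PRRX1 (0.64) rose, 15 did not pass, and the camera adjusted p was 0.82. SNAI2, a repressor of epithelial genes, differed by 1.05 and the fibroblast activation protein FAP by -1.23 (limma adjusted p of 0.082 and 0.081). Of 6 epithelial and junction genes that were measured, KRT7 rose and 5 did not pass, among them JUP (0.62) and CLDN5 (-0.90), with a camera adjusted p of 0.23. Adjusted over the list alone, 4 rose and 3 fell in the mesenchymal list and 3 rose and 1 fell in the epithelial list.

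Of 26 measured receptor tyrosine kinases and growth factors, 2 rose and 6 fell (camera adjusted p = 0.23; adjusted over the list alone, 3 rose and 9 fell). The ligand PDGFA fell by 3.12, from 9.78 ± 0.04 (SD, n = 2) to 6.66 ± 0.37, IGFBP5, a binding protein of insulin-like growth factors, by 1.54 and the receptor FGFR1 by 1.37, whereas the ephrin receptor EPHA3 rose by 1.30. VEGFA (-1.29) and EPHA2 (-1.13) did not pass. In the Wnt list 5 of 19 members rose and 2 fell (camera adjusted p = 0.34; adjusted over the list alone, 5 and 2). RSPO3, a secreted enhancer of Wnt signalling, fell at least 29.1-fold and the ligand WNT5B by 1.87. The receptor FZD4 rose at least 8.64-fold and the co-receptor LRP5 at least 2.01-fold, while FZD9 (-0.70) and LGR4 (0.64) did not pass. In the TGF-beta and BMP list 1 of 28 rose and 3 fell (camera adjusted p = 0.89; adjusted over the list alone, 1 and 3). BAMBI, a decoy receptor of this pathway, fell by 2.73, SKIL by 1.42 and NBL1 by 0.73. Of the 3 tested probe sets of SKIL, 1 was lower by 0.05 and did not pass (limma adjusted p = 0.93). TGFB1 rose by 1.26, and SMAD7 (-1.19) and INHBA (higher by at least 1.58-fold) did not pass. Of 9 Notch genes (camera adjusted p = 0.84; adjusted over the list alone, 1 rose and 1 fell) the target HEY1 fell by 1.11, and LFNG (1.08) and JAG1 (lower by at least 1.32-fold) did not pass. Of 14 cytokine and chemokine genes 2 rose and 5 fell (camera adjusted p = 0.83; adjusted over the list alone, 3 and 5), with falls of 2.28 for SOCS2, 2.03 for IL16, 1.46 for TNFAIP6 and 1.40 for the chemokine IL8L2. CISH (2.09) and TNFSF10 (0.85) did not pass.

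No shift was detected in the lists of proliferation genes. None of 51 mitosis and G2/M genes passed singly or adjusted over the list alone (median 0.03, camera adjusted p = 0.83), and BIRC5 (0.76) and CENPE (-0.62) were farthest from 0. Of 56 S phase and replication genes 1 rose and 4 fell (median 0.01, camera adjusted p = 0.71; adjusted over the list alone, 1 and 4), among the latter CCND2 (-0.75), GINS3 (-0.72) and RFC4 (-0.53), and UHRF1 (0.67) and E2F1 (-0.55) did not pass. CDKN1A, the cyclin-dependent kinase inhibitor p21, is in this list and in the p53 list and fell at least 3.92-fold. Of 34 genes of the p53 and DNA damage response 2 rose and 4 fell (camera adjusted p = 0.50; adjusted over the list alone, 2 and 7). The kinase PLK2 rose by 3.37 and the sestrin SESN3 at least 7.15-fold, the damage sensor DDB2 fell at least 3.17-fold, and TP53INP1 (0.93) and ATR (-0.89) did not pass. Of 60 ribosomal protein genes RPL37 (0.57) and RPL13 (0.44) rose, 58 did not pass, RPS21 (0.43) and RPLP0 (-0.42) among them, and 1 rose when adjusted over the list alone (median 0.06, camera adjusted p = 0.23). None of 12 genes of the RNA interference machinery passed, over all genes or adjusted over the list alone (camera adjusted p = 0.84), with DICER1 at 0.43 and DGCR8 at -0.41.

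Stress and metabolic genes changed singly. In the hypoxia and glycolysis list 2 of 38 rose and 2 fell (camera adjusted p = 0.78; adjusted over the list alone, 4 and 4). EPAS1, the hypoxia-inducible factor 2 alpha, fell at least 12.2-fold and the lactate transporter SLC16A3 by 0.65, whereas the peptide hormone ADM (1.63) and NDRG1 rose. The carbonic anhydrase CA9 differed by -1.65 (limma adjusted p = 0.074). Of 31 genes of the unfolded protein and amino acid response 5 rose and 4 fell (camera adjusted p = 0.61; adjusted over the list alone, 6 and 7). The amino acid transporter SLC7A5 fell at least 7.13-fold, PSAT1 rose by 1.60, VLDLR by 1.43 and GARS by 1.03, and DNAJB9 (-0.95) and CRELD2 (-0.71) did not pass. Of 34 heat shock and oxidative stress genes 3 rose and 2 fell (camera adjusted p = 0.83; adjusted over the list alone, 5 and 3). The glutathione transferase GSTA3 rose 4.77-fold and the collagen chaperone SERPINH1 2.84-fold, the metallothioneins MT3 and MT4 fell by 1.06 and 0.98, and HSPB1 (0.66) and CAT (0.57) did not pass. The sign of the median opposed that of the mean or of the camera test, in every case with a median within 0.1 of 0 except for the cytokines (median 0.32, mean -0.15), in the lists of S phase, cytokine, matrix protease, metastasis suppressor, heat shock, Notch, endothelial and TGF-beta genes.

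Markers of other cell types were mostly near the background. Of the 40 markers of macrophages and blood cells on the array 9 were measured, and 2 rose, C1QB and the scavenger receptor CD36 (at least 3.59-fold), while 2 fell, LAPTM5 (-1.71) and CD3D (-1.11). CD247 (0.82) and ALAS1 (-0.76) did not pass, and 4 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.61). The list as fixed names ALAS2, and ALAS1 entered it through the matching of symbols, so this member may not mark blood cells. Of 9 neural, glial and melanocyte markers measured 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.23). MITF, the regulator of melanocyte identity, fell at least 4.02-fold and the synaptic vesicle protein SYT1 at least 4.13-fold, and NEUROD1 (lower by at least 1.47-fold) and NES (-0.39) did not pass. Of 6 cartilage, bone and fat markers SOX5 rose at least 1.72-fold and FABP4, a fatty acid binding protein, differed by 2.30 (limma adjusted p = 0.067) and PPARG by 0.48 (limma adjusted p = 0.50), and 2 rose when adjusted over the list alone (camera adjusted p = 0.61). Of 15 targets of SRF and muscle genes MYH10 (0.88) rose and CNN2 (-0.98) fell, MYL9 (0.65) and MYH9 (-0.62) did not pass, and 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.84). None of 6 endothelial markers and none of 16 HOX genes passed, over all genes or adjusted over the list alone (camera adjusted p of 0.89 and 0.83); the largest differences were -0.90 for CLDN5, 0.77 for PROX1, 1.10 for HOXD4 and 0.80 for HOXC9. For 14 of the 115 called genes named in the text, 1 or 2 other tested probe sets did not pass, with the same sign in each case (AADAC, POSTN, SKIL, PTK2, SESN3, ELOVL5, ELOVL6, MYH10, NBL1, NDRG1, PRRX1, RFC4, GSTO2 and GSTT1). Of the 115 genes, 38 still passed without control replicate 1 and 32 without control replicate 2, against 109 and 109 without anti-HOPX replicates 1 and 2, and 41 with no filter on low values.

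**Figure D2:**
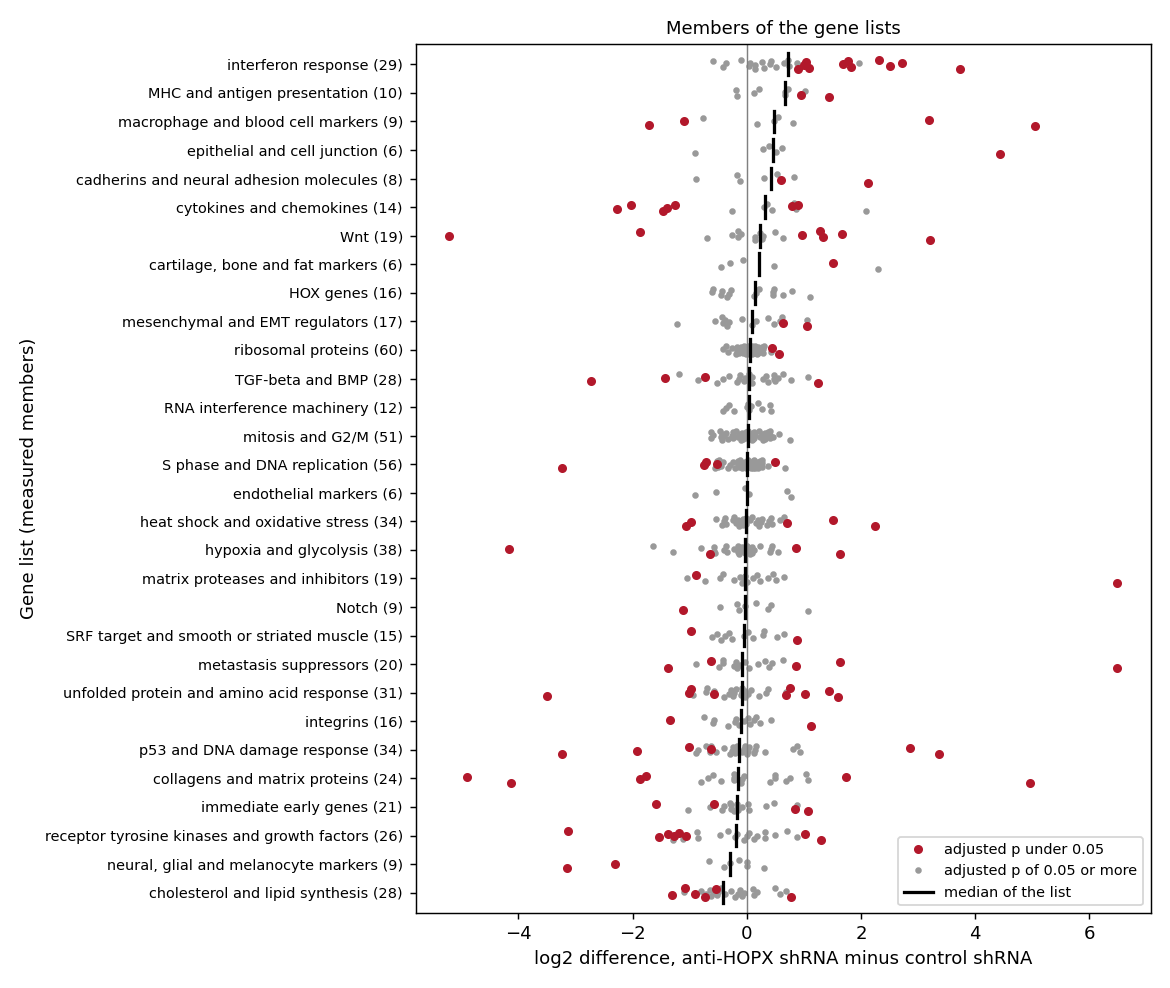
Log2 difference (anti-HOPX minus control, horizontal axis) of each measured member of the gene lists described here, with the number of members in brackets, red points for members with adjusted p under 0.05, grey points for the others and a black bar at the median of each list. The medians run from -0.41 for cholesterol and lipid synthesis to 0.73 for the interferon response, and in most lists the members that passed lie on both sides of 0.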

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

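The counts of changed probe sets moved most without a control array, then with the threshold and the filter. Leaving out each array in turn gave 34 to 461 higher and 108 to 664 lower probe sets, with 34 and 108 without control replicate 2 and 39 and 115 without control replicate 1, where the spread comes from the anti-HOPX arrays alone. With no filter on low values 71 probe sets were higher and 182 lower, with a mean of at least 6 the lower count was 329, at an adjusted p under 0.01 the counts were 76 and 170, by limma's treat against a log2 change of 1 they were 46 and 136, and as genes 185 and 306 when adjusted over genes alone. The stricter filter tests fewer probe sets, and the cause of the other moves was not tested. Leaving out each array in turn, HOPX ranged from -0.34 to 0.15, with both 0.15 (without control replicate 2) and 0.07 (without anti-HOPX replicate 1) of the other sign, and its difference has no value with values under 4 raised to 4. The count of higher lists, 2, was 1 with a mean of at least 6, 1 without probe sets ending in _x_at, _s_at or _a_at and 0 with an estimated correlation and by fry (against no change), which also left 0 lower. Leaving out each array gave 1 to 2 lists higher and 0 to 1 lower. The robust variance model has no list result of its own. GAPDH turned to -0.018 with quantile normalisation. Of the 1555 values of the 184 named genes under the settings other than leaving out an array, 1368 kept their sign and side of the threshold, 119 lost the call, 67 gained it and 1 turned. Leaving out an array turned the sign of 9 named genes that did not pass, with ranges of -0.28 to 0.079 for C4, -0.0089 to 1.42 for C1R, -0.019 to 0.030 for CR1, -0.0039 to 0.17 for C6, -0.18 to 0.58 for GSTA2, -0.48 to 0.15 for GSTT1L, -1.37 to 0.047 for NEUROD1, -0.023 to 0.99 for PPARG and -0.84 to 0.0096 for DGCR8. The replicate numbers are shared by both forms, but the labels give no shared batch, so they are only numbers. With the replicate block, 436 probe sets were higher and 680 lower and the lists stayed at 2 and 1; same-numbered arrays deviated together with r = 0.25 across probe sets.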

Other observations

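Tests of the interferon and chromosome patterns, of runs of neighbouring genes and of other splits of the arrays were chosen after the results were seen, as were, for the genes near the floor, the count of nearest genes called lower and the comparison with other probe sets. The counts of adjacent genes near the floor were set earlier. Members of 3 gene families were looked at after their values were seen and were not tested as groups. Of 15 keratins on the array, 2 had a control mean of 4 or more, KRT75 and KRT14, and both rose. KRT75, a type II keratin, went from 7.46 ± 0.02 (SD, n = 2) to 11.50 ± 1.15, KRT14, the partner of KRT5 in basal epithelium, rose by 2.18. Another 4, KRT5, KRT7, KRT75L2 and KRT23, had control means under 4 and were measured only because of their anti-HOPX values, so that they rose says nothing of the family (KRT75L2 at least 8.59-fold and KRT23 at least 3.80-fold), and 9 were not measured. Keratins have near-identical copies, so which of them gave the signal is uncertain, and KRT75, KRT75L2, KRT7 and KRT14 lost their calls without control replicate 1 and, with KRT23, without control replicate 2. Of 21 complement genes on the array, 6 had a control mean of 4 or more, of which the receptor CR2 rose (3.06, limma adjusted p = 0.0028) and 5 did not pass (C4, C1R, C1S, CR1 and C6). C1QB and CFI were measured only because of their anti-HOPX values, and 13 were not measured. Of 9 glutathione transferases, GSTA4 (3.04), GSTA3 and GSTZ1 (0.88) rose, GSTO2 (-1.08) and GSTT1 (-0.59) fell, and GSTA2, GSTK1, GSTM2 and GSTT1L did not pass. None of these 5 calls held without control replicate 1 or without control replicate 2, nor with no filter on low values.

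In 25 genes the mean went from 7 or more in control to under 4 in anti-HOPX cells, against 14 genes the other way, and a candidate explanation is the loss of DNA segments in the anti-HOPX cells. Among the 24 genes that could be placed on GRCg7b, 0% lay next to another such gene among the expressed genes, an upper 95% bound of 14.2%, which argues against segments that silence several neighbouring genes for most of them, and there were 0 adjacent pairs against 1 at the upper end of the middle 95% of random placements. That count looked only at neighbours near the floor, however. Of 140 nearest genes 12 were called lower, against a median of 5 and an upper end of 10 in random placements (permutation p = 0.0098). Of the 12, 4 were at FBLN1 and 3 at OSBPL6, on chromosomes that were lower as a whole (medians -0.19 and -0.31). These 2 genes were picked after the counts were seen, so the remaining 5 cannot be set against the random placements. The median difference of the nearest genes was -1.20 at FBLN1 and -0.91 at OSBPL6, against -0.41 to 0.28 at the other genes. The shifts of the 2 chromosomes were smaller than that but may add to the count. Smaller losses around these 2 genes cannot be told apart from regulation. Of the 29 genes with any such probe set, 9 had 1 other probe set that was measured in control and was not near the floor itself, and 8 of these 9 (88.9%, exact 95% interval 51.8 to 99.7%) were lower by at least 1, which argues against a fault of single probe sets for most of these 9 (not ATAD1), and for NUDT14, FBLN1, RSPO3 and SLC22A3 both of 2 probe sets fell from 7 or more to under 4, with falls of at least 3.33 at the floor of 4. A fault of single probe sets stays open for the other 16 genes, MVP, DHRS7, TMEM26 and RAB15 among them, as do silencing of single genes, insertion of the vector and a difference that existed between the transfected cells. The 2 probe sets of SLC22A3 have names that differ only in the suffix. So do the compared probe set of JMJD7, 1 of the 9 genes, and 1 of its probe sets near the floor. Such pairs may share a target sequence and thus a fault.

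The interferon list was higher in all 4 pairs of an anti-HOPX and a control array. Its lowest median over the pairs was 0.40, against 0.22 at the upper end of the middle 95% of random lists matched on level, so its direction does not rest on a single array. The median was 1.05 and 1.01 with anti-HOPX replicate 1 and 0.42 and 0.40 with replicate 2. Random lists were not matched on how far their genes move together (estimated correlation 0.30 for the interferon list). Their range therefore does not measure how this list varies between arrays. Of the 33 blood cell markers that were under 4 in control, 2, C1QB and CD36, reached 5 or more in anti-HOPX cells (6.06%, exact 95% interval 0.74 to 20.2%). The markers belong to several kinds of blood cell. A single kind could not have raised most of them, so this share does not exclude it. PTPRC, a marker of all white blood cells, read 2.78 in control and 2.75 in anti-HOPX cells and gave no sign of white blood cells. A response to the hairpin RNA, to the culture or to a difference between the transfected cells remains a hypothesis that these arrays do not test, because no form without an shRNA was analysed here.

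Genes of the same chromosome tended to shift together. Of 28 chromosomes with at least 60 measured genes in GRCg7b, 7 had a lower and 14 a higher median difference than random placements of the genes gave (adjusted p under 0.05, 2000 placements). The arrays are normalised to each other and the placements use the same genes, so each shift is relative to the other chromosomes. Higher medians therefore cannot be told apart from a counterpart of the lower ones. On the chromosome that carries P2RX4 the median of 221 genes was -0.38 and 84.2% of them were below 0, on that of OSBPL6 and COL18A1 it was -0.31 over 262 genes, and on that of CR2 it was 0.20 over 122 genes. A single array is argued against for most of them, since 17 kept their sign outside the random range in all 4 pairs of arrays, but not for the other 4. Trends with level and gene length are argued against by 20 that stayed past the threshold after both were removed. A few strong genes can hardly move a median over at least 60 genes. That called genes were as many as the excess of genes on the shifted side on 0 chromosomes therefore adds no separate support. Different chromosome copy numbers in the 2 transfected forms may account for such shifts, which would make part of the differences between the arrays a property of the cells that were grown out rather than of HOPX, and a trend with GC content stays open because no genome sequence was used here.

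Called genes were also neighbours more often than by chance, with 24 adjacent pairs of higher genes against a median of 4 in random orders and 23 of lower genes against 11 (permutation p = 0.0002, the smallest that 5000 orders can give, and 0.0008). Part of this follows from the shifts of whole chromosomes, and with orders drawn within each chromosome the medians were 7 and 13 (permutation p = 0.0002 and 0.0058). The longest run of higher genes held 5 neighbours, STX8, FAM18B1, PMP22, COX10 and METRNL, each higher by at least 2-fold, but 0 of the 5 passed without control replicate 1 or without control replicate 2. Without control replicate 1 or without control replicate 2 no excess was seen, with 0 to 1 adjacent pairs. Far fewer genes were called there, and whether this accounts for the loss was not tested. Without anti-HOPX replicates 1 and 2 there were 27 pairs of higher genes against a median of 4 in genome-wide random orders and 28 against 9. For lower genes there were 36 pairs against 18 and 22 against 14. The real split of the 4 arrays gave 814 changed probe sets and was 1 of 3 possible splits into 2 and 2, of which the highest other gave 0. Each other split puts 1 array of each form in each group, so the difference between forms enters its spread and hinders calls. The 0 therefore cannot show that the 814 did not arise by chance, and 3 splits are too few for a share under 0.05.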
